A study of Mus musculus with 60 samples.

How the data were processed

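Per the labels' protocols, RNA from ovaries and testes was made into stranded poly(A) libraries with a KAPA mRNA HyperPrep kit and sequenced as paired-end reads on an Illumina HiSeq instrument. Per the submitters' processing notes, FastQC 0.11.33 was used and the genome build was GRCm38. The notes name no aligner and no counting tool; only the names of the deposited files point to EMASE-Zero, without a version. Per the file headers, each of the 60 deposited tables holds the authors' expected counts for each transcript, per B6 and CAST haplotype and as their sum. Sums per gene were rounded to whole numbers.

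From there, the 115125 transcripts of each table were matched by identifier to GENCODE M21 (GRCm38), which found 114237 of them (99.2%), and summed to 47348 genes. The 2 libraries of each biological replicate were summed, as planned from their titles before the data were examined, and their counts differed little (median chi-square per degree of freedom 2.24 over 30 pairs, against 25.0 over 60 pairs of replicates). This left 30 replicates, 5 in each of 6 groups, with totals of 13.6 to 31.1 M expected counts. One CAST label spells its tissue in a way that was read as testis, and its counts differed from those of the other library of its replicate no more than the pairs at large (at most 2.78). Levels are given as CPM over all genes of a replicate, without TMM factors, which entered the tests only.

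Groups were compared with edgeR 4.0.16 (quasi-likelihood F tests, TMM factors, filterByExpr with a count minimum of 10 and a total of 15, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The strain comparisons used the 15 replicates of a tissue, and the tissue and strain-by-tissue comparisons all 30. Errors of log2 fold changes are SE, all other errors are SD over 5 replicates. The allelic test within F1 fitted the B6 and CAST counts of each replicate with edgeR and a term for the replicate, over autosomal genes with a mean of at least 20 allelic counts and a B6 allele share of at least 90% in B6 and at most 10% in CAST. The same model with the parental strains added tested whether the ratio between parents differed from the ratio between alleles. Gene lists (29 lists, 431 genes, 429 of them found) were fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternatives, except where the text says otherwise. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

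By the naming rule, Kif18a and the APC/C subunits are always named. Beyond those, up to 8 genes at either end of a comparison qualify (protein coding, a mean of at least 10 CPM in the higher group, replicates that do not overlap). Up to 2 at either end of each list, 5 at either end on chromosome 5 (at least 5 CPM), 5 at either end for the strain-by-tissue, parental mean and parent against allele comparisons and 8 at either end for alleles (at least 100 allelic counts) also qualify, with the informative imprinted genes. Genes past the threshold within 2 Mb of Anapc5 and Anapc7 are open to naming too. The cell type markers shown per replicate were picked from the lists after their values were seen.

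The power of each comparison was measured on simulated negative binomial counts, with the totals and dispersions of the data and known changes in randomly drawn genes. With CAST against B6 in ovary, 70.0% of 2-fold and 93.0% of 4-fold changes passed, and 3.55% of calls were false. In testis 32.0% and 79.2% passed, for alleles 59.0% and 93.0% in ovary and 63.0% and 86.0% in testis, and for parents against alleles in testis 7.00% and 54.0%. Parents against alleles in ovary had the highest share of false calls (12.2%). The simulated genes varied independently and no replicates of a group stood apart, so these shares may not hold for groups whose replicates do.

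The alternatives were DESeq2 1.42.0, RLE factors, no filter or a mean CPM of at least 1, a log2 change of at least 1, only 1 library of each pair, each replicate left out, all 30 replicates or only the compared groups in a fit, and, for alleles, other informative filters and limma on log2 ratios with a pseudocount of 0.5. Leaving out ovary B6 replicates 2, 3 and 4, ovary B6 replicates 1 and 5 and testis CAST replicates 4 and 5, and dropping ribosomal RNA-like loci, which took 0.840% to 11.2% of counts, were chosen after seeing the data. Genes on the X chromosome and the mitochondrial genome were left out of the allelic tests, because males carry a single X and both sexes carry maternal mitochondria. Intervals and floors cover counting error only.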

Results

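Poly(A) RNA was measured by sequencing in ovaries and testes of C57BL/6J mice (B6), of CAST/EiJ mice (CAST, an inbred strain of wild Mus musculus castaneus origin) and of F1 offspring from B6 mothers and CAST fathers. Ovaries came from fetuses at 12.5 to 13.5 days post coitum and testes from pups at 5 days post partum, ages at which, by the series' design text, dividing germ cells are abundant. The stated purpose was to see how the genes of a chromosome 5 interval are expressed in these tissues, and the series title names the anaphase promoting complex (APC/C) and the kinesin KIF18A. Each of the 6 groups held 5 biological replicates, and each replicate was the sum of 2 libraries. The totals were 13.6 to 31.1 M expected counts per replicate and 6.69 to 15.9 M per library. The CAST allele made up 3.80 ± 0.0857% (SD, n = 5) of autosomal allelic counts in B6 ovary, 96.3 ± 0.104% in CAST ovary and 49.5 ± 0.465% in F1 ovary. In testis the same shares were 3.63 ± 0.103%, 96.3 ± 0.121% and 49.2 ± 0.160%.

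Within 2 groups the replicates did not form a single cloud, and the genes that set them apart were those of germ cells and of several somatic lists. Ovary B6 replicates 2, 3 and 4 held 48.1, 38.5 and 16.6 CPM of Stra8, the retinoic acid target that marks entry into meiosis, against 0.0973 CPM in replicate 1 and 0 in replicate 5. In the same replicates the germ cell helicase Ddx4 stood at 99.1, 75.8 and 84.1 CPM, against 7.74 and 3.55 CPM in replicates 1 and 5, and the pregranulosa factor Foxl2 at 8.24, 6.70 and 5.47 CPM against 1.22 and 0.383 CPM. The F1 ovaries held 22.6 ± 6.49 CPM of Ddx4 (SD, n = 5) and the CAST ovaries 5.77 ± 1.47 CPM. Testis CAST replicates 4 and 5 held 383 and 310 CPM of Sycp3, a protein of the meiotic chromosome axis, and 647 and 579 CPM of Ddx4. Their level of Amh, a hormone of immature Sertoli cells, was 10.6 and 9.56 CPM, against 363 ± 32.2 CPM in B6 testis (SD, n = 5). In the median of a list, these 2 lay below the other CAST testes by log2 ratios of -3.15 for stroma, -3.37 for mesonephros, -1.985 for endothelium and -2.14 for peritubular genes, and ovary B6 replicates 2, 3 and 4 lay below replicates 1 and 5 by -2.40 for neural crest genes. These 5 replicates stayed in every main comparison, and the number of genes that differed is also given without them, an alternative chosen after seeing the data.

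**Figure D1:**
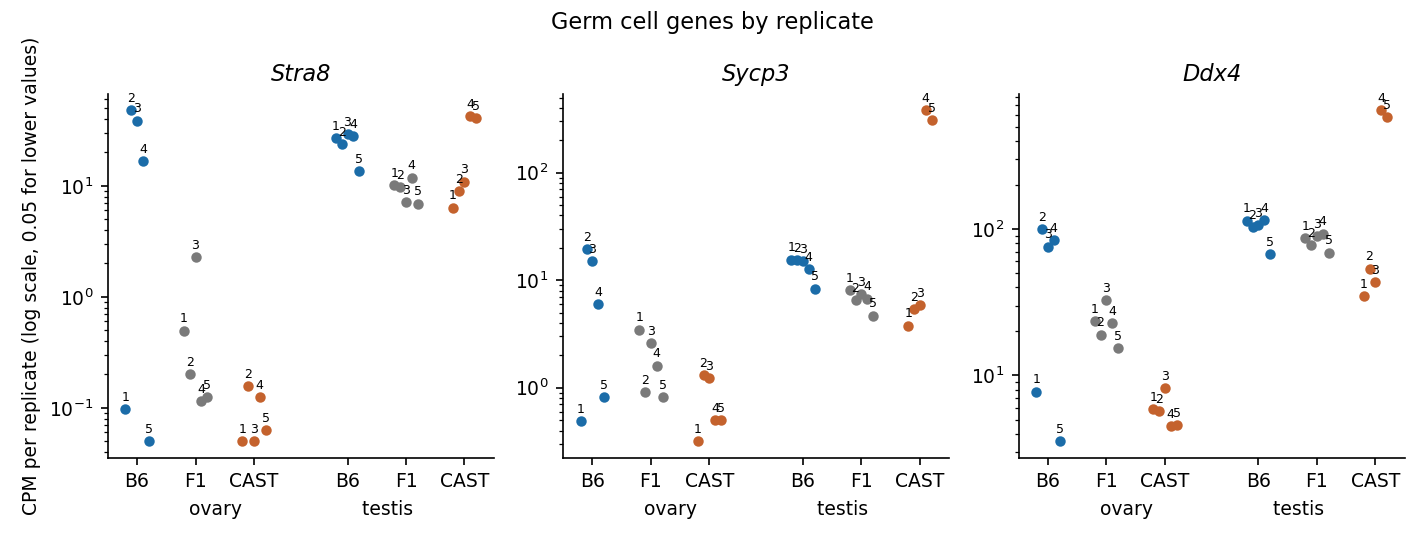
Level of the germ cell genes Stra8, Sycp3 and Ddx4 (CPM, log axis, values under 0.05 drawn at 0.05) in each of the 30 replicates, by group. Stra8 reached 48.1 CPM in ovary B6 replicate 2 and 0.0973 CPM in replicate 1, and Sycp3 reached 383 CPM in testis CAST replicate 4.

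Kif18a, the kinesin that limits chromosome movements at the spindle equator, was expressed at similar levels in all 6 groups. Kif18a (ENSMUSG00000027115, GRCm38 chromosome 2, 109280738 to 109341747) measured 22.5 ± 4.07 CPM in B6 ovary, 20.9 ± 3.48 CPM in F1 ovary and 20.9 ± 1.97 CPM in CAST ovary (SD, n = 5 each). In testis it measured 25.2 ± 3.10, 24.98 ± 2.97 and 21.7 ± 4.23 CPM in the same order. The strain difference did not pass edgeR's quasi-likelihood test in ovary (log2 fold change of CAST over B6 -0.06 ± 0.13 SE, adjusted p = 0.744) or in testis (-0.07 ± 0.18, adjusted p = 0.780). Without testis CAST replicates 4 and 5 it passed in testis, with Kif18a lower in CAST (log2 fold change -0.45, adjusted p = 0.00244 by edgeR). Most mitotic kinesin genes and all shared germ cell genes fell in that comparison too, so the fall was not particular to Kif18a.

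Of the 14 measured APC/C subunit genes, 2 fell in CAST ovary and 12 did not pass, by small amounts, and 1 passed when adjusted over the list alone. Anapc5 (ENSMUSG00000029472, chromosome 5, 122787459 to 122821339), a scaffold subunit of the complex, fell from 464 ± 37.2 CPM in B6 to 394 ± 16.4 CPM in CAST ovary (log2 fold change -0.195 ± 0.045, adjusted p = 0.00344), with 426 ± 11.4 CPM in F1. Anapc16 fell by 0.17 on the log2 scale (adjusted p = 0.0388), a call lost on leaving out any of 7 of the 10 replicates: B6 replicates 2, 3 or 5 or CAST replicates 1, 2, 3 or 4 (adjusted p = 0.0675 to 0.0970). Anapc7 (ENSMUSG00000029466, chromosome 5, 122421693 to 122444912), the other subunit gene of that region, measured 69.6 ± 3.402 CPM in B6 and 71.4 ± 2.80 CPM in CAST ovary (log2 fold change 0.07 ± 0.055, adjusted p = 0.307). Anapc5 lost its call without ovary B6 replicates 2, 3 and 4 (log2 fold change -0.11, adjusted p = 0.183) and when all 30 replicates were fitted together (-0.18, adjusted p = 0.165), with a range of 4.08e-05 to 0.183 over the settings tried. The list as a whole gave a camera adjusted p of 0.854, with adjusted p = 0.938 with an estimated correlation.

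In CAST testis 2 APC/C subunit genes rose and 4 fell against B6, 4 and 4 when adjusted over the list alone. Anapc15, which frees the APC/C from checkpoint inhibition, fell from 69.7 ± 5.90 to 40.1 ± 5.95 CPM (log2 fold change -0.67 ± 0.15, adjusted p = 0.00501 by edgeR). Cdc23 (-0.48), Anapc1 (-0.41) and Anapc2 (-0.21) fell too, and all 4 stayed past the threshold without CAST replicates 4 and 5, at -0.94 for Anapc15 and -0.25 for Cdc23. The rises of Anapc11 (0.46) and Cdc27 (0.38) were lost without those replicates (adjusted p = 0.267 and 0.224), where Cdc16 (0.34) and Cdc26 (0.24) were higher instead. Anapc2 also lost its call without B6 replicate 2 or 3 (adjusted p = 0.0502 and 0.0523), Anapc11 without any B6 replicate or CAST replicate 4 or 5 (0.0773 to 0.125), and Cdc27 without B6 replicate 1, 2, 3 or 5 or CAST replicate 4 or 5 (0.0713 to 0.116). Anapc5 measured 398 ± 27.5 CPM in B6, 418 ± 23.4 CPM in F1 and 342 ± 106 CPM in CAST testis (log2 fold change -0.14 ± 0.12, adjusted p = 0.367). Anapc7 was at 57.7 ± 3.93 CPM in B6 and 63.4 ± 3.24 CPM in CAST testis (0.26 ± 0.10, adjusted p = 0.0562). It passed without CAST replicate 1, 2 or 3 (adjusted p = 0.0335, 0.0387 and 0.0236) or by DESeq2 (adjusted p = 0.0413; 0.00814 to 0.228 over the analysis settings tried).

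**Figure D2:**
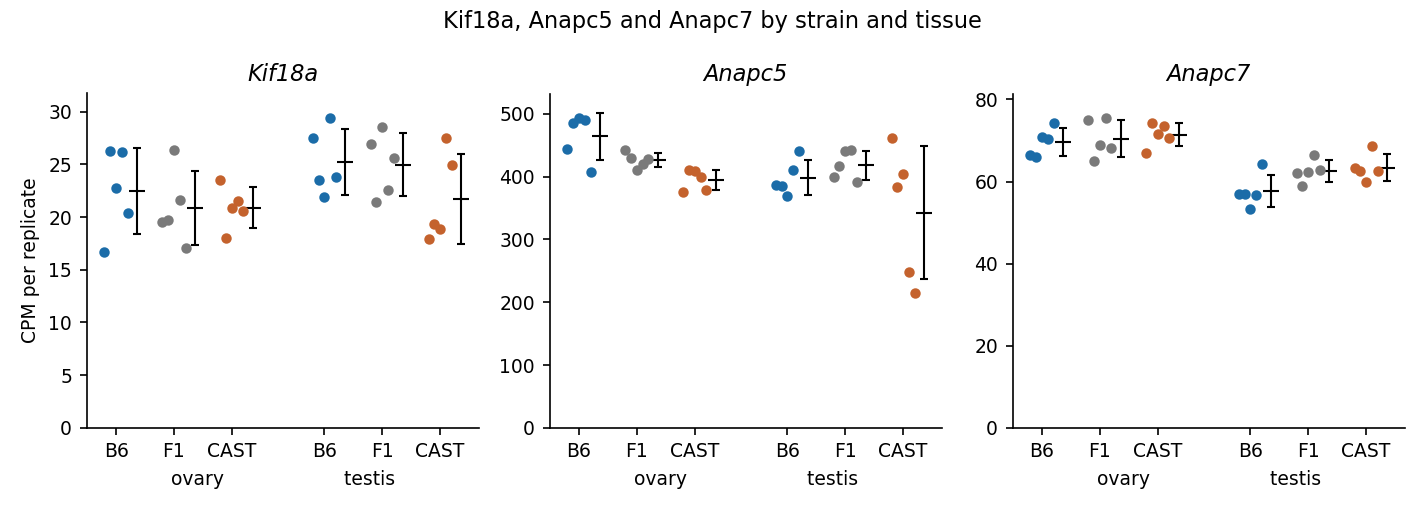
Level in CPM of Kif18a, Anapc5 and Anapc7 in each replicate, with the mean and SD of each group of 5. Anapc5 averaged 464 CPM in B6 ovary and 394 CPM in CAST ovary, and its spread was widest in CAST testis (SD 106 CPM).

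With all replicates, the CAST ovary had lower levels of genes of meiosis and of ovarian supporting cells than B6, mostly through B6 replicates 2, 3 and 4. A few cell cycle and interferon genes were higher, and others of these kinds were lower. At an adjusted p under 0.05, 6650 of 17336 genes differed, 3076 higher and 3574 lower in CAST, of which 727 and 1377 by at least 2-fold. With all 30 replicates in one fit the count was 3794, and by DESeq2 7462. In the meiotic onset list 13 of 19 measured genes fell and 6 did not pass (15 fell adjusted over the list alone; camera adjusted p = 0.00558, adjusted p = 0.795 with an estimated correlation). Rec8, the meiotic cohesin, fell from 41.1 ± 20.2 to 0.848 ± 0.188 CPM (log2 fold change -5.54 ± 0.41), Syce1 of the synaptonemal complex fell by 4.58 on the log2 scale and Hormad1, of the shared germ cell list, by 3.44. Among pregranulosa genes 10 of 15 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.00558, adjusted p = 0.795 with an estimated correlation), including Foxl2 (-3.94 ± 0.69). Mesonephros and duct genes fell in 8 of 13 (9 adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.795 with an estimated correlation), such as the keratin Krt19 (-1.85) and the cadherin Cdh16 (-1.54), whose call was lost with all 30 replicates in the fit (adjusted p = 0.234; 1.79e-08 to 0.234 over the settings tried).

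These lists moved with ovary B6 replicates 2, 3 and 4, where the median member was higher than in B6 replicates 1 and 5 by a log2 ratio of 2.64 for meiotic onset, 1.02 for pregranulosa and 0.95 for mesonephros. Without those 3 replicates, 3061 genes differed (1460 higher, 1601 lower), and without replicates 1 and 5 the count was 8723. In the smaller comparison 4 meiotic onset genes rose and 2 fell, 1 pregranulosa gene and 4 mesonephros genes fell. There, 11 of 16 fetal germ cell and pluripotency genes rose (12 adjusted over the list alone; camera adjusted p = 4.00e-08, adjusted p = 0.319 with an estimated correlation). Rec8 stayed lower (-4.61), while Foxl2 (-1.55, adjusted p = 0.0846 by edgeR), Syce1 (-1.16, adjusted p = 0.272) and Hormad1 (-0.22, adjusted p = 0.818) lost their calls.

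Cell division genes moved in both directions in CAST ovary. In this comparison 38.4% of all tested genes passed, so a count near that share is not particular to a list. The cell division and interferon lists were not among those that camera called. In the DNA replication list 7 of 20 genes rose and 13 did not pass (7 adjusted over the list alone; camera adjusted p = 0.0524), and none of the 20 rose or fell by edgeR without B6 replicates 2, 3 and 4. Among mitotic cyclins and kinases 5 of 17 rose, 3 of them adjusted over the list alone, and in the kinetochore list 9 of 28 fell and 2 rose, including Spc25 of the Ndc80 complex (-0.40 ± 0.07, adjusted p = 0.000330). Cdc20, the mitotic coactivator of the APC/C, rose from 76.3 ± 6.83 to 106 ± 11.5 CPM (log2 fold change 0.51 ± 0.09), and the securin gene Pttg1, an APC/C substrate, rose by 0.80 ± 0.08. Both held without B6 replicates 2, 3 and 4 (0.40 and 0.86), although the rise of Cdc20 was lost with all 30 replicates in the fit (adjusted p = 0.0774; 1.15e-06 to 0.0774 over the settings tried). The interferon response list had 5 of 17 genes higher and 2 lower, with Mx1 and Mx2 at 13.9 ± 12.9 and 29.3 ± 24.7 CPM in CAST and 0.210 ± 0.230 and 0.427 ± 0.236 CPM in B6. Among the largest contrasts, Eno1b (8.81) and Hmga1b (7.78) were higher in CAST, Entpd4b was at least 651-fold and Hyal4 at least 387-fold higher, and Tmem254b and Tmem254c were at least 529-fold and 520-fold lower. Each of those limits comes from a floor of 3 counts over the group at 0. Whether the counting told related gene copies apart was not tested.

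Chromosome 5 did not stand out from the other autosomes in the share of genes that differed between the strains. The labels do not give the limits of the study's interval, so the whole chromosome and a window around Anapc5 and Anapc7 were described instead. In ovary 38.5% of its 1211 tested genes passed, against 38.4% of 15500 genes on the other autosomes (two-sided Fisher's exact test, p = 0.976), and in testis 33.2% of 1234 against 32.6% of 15668 (p = 0.659); genes are not independent replicates. Without ovary B6 replicates 2, 3 and 4 the shares were 18.2% against 16.8% (p = 0.187), and without testis CAST replicates 4 and 5 they were 43.6% against 44.5% (p = 0.562). The chromosome 5 genes with the largest rises in CAST ovary included Acad12 and Acad10, of the acyl-CoA dehydrogenase family, at 24.7 ± 0.756 against 7.02 ± 1.18 CPM and 12.6 ± 1.44 against 5.10 ± 0.433 CPM. Ereg, the growth factor epiregulin, fell from 8.42 ± 2.07 to 0.0617 ± 0.0632 CPM, and the meiotic genes Stag3 (-4.28), Hfm1 (-2.87) and the checkpoint gene Rad9b (-3.37) fell with it. Stag3 and Hfm1 had smaller falls without ovary B6 replicates 2, 3 and 4 (-2.22 and -1.084). In testis Acad10 (1.81 ± 0.15) and Acad12 (1.17 ± 0.11) were higher in CAST as well.

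Within 2 Mb of Anapc5 and Anapc7, from position 120421693 to 124821339, 17 of 107 tested genes were higher and 25 lower in CAST ovary, and 32 of 114 were higher and 14 lower in CAST testis. Over all tested genes 38.4% passed in ovary and 32.3% in testis, and the window was not tested against the rest. Without ovary B6 replicates 2, 3 and 4, 9 of 112 were higher and 11 lower, and without replicates 1 and 5, 25 of 111 were higher and 21 lower. Without testis CAST replicates 4 and 5, 28 of 119 were higher and 23 lower. Camkk2, a kinase gene of this window, fell by 0.54 ± 0.06 on the log2 scale in ovary and by 1.56 ± 0.16 in testis. Snrnp35, of the minor spliceosome, rose by 0.98 ± 0.08 in ovary and by 2.10 ± 0.41 in testis, or 0.95 in testis without CAST replicates 4 and 5. The ATP receptor gene P2rx4 fell by 0.96 in ovary, and Iqcd rose by 4.65 in testis.

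**Figure D3:**
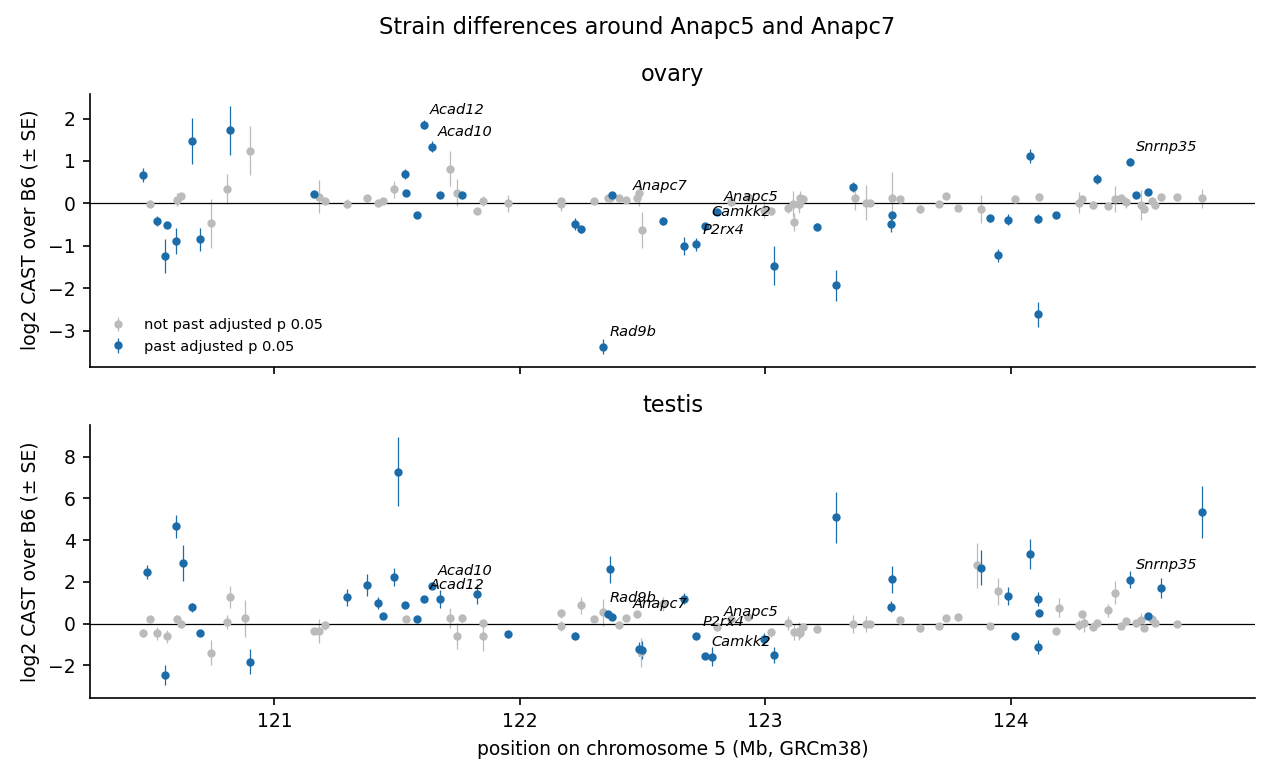
Log2 fold change of CAST over B6 for each tested gene within 2 Mb of Anapc5 and Anapc7, by position on chromosome 5 (GRCm38), in ovary and testis. Genes past an adjusted p of 0.05 are marked, 17 higher and 25 lower in ovary and 32 higher and 14 lower in testis.

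Single meiotic and axoneme genes were higher in CAST than in B6 testis, mostly through CAST replicates 4 and 5. Spag17 measured 321 and 354 CPM there, against 1.31, 2.15 and 1.38 CPM in CAST replicates 1, 2 and 3. Sycp3 measured 3.78, 5.35 and 5.82 CPM in CAST replicates 1, 2 and 3, below the 8.37 to 15.5 CPM of B6 testis. Of 17638 tested genes 5695 passed, 3555 higher and 2140 lower, and 2230 and 871 differed by at least 2-fold. Among the strongest rises were Fbp1, a gluconeogenic enzyme (10.24), and the ciliary axoneme genes Spag17 (8.83), Rsph1 (8.49) and Cfap58 (8.47). Rsph1 averaged 1116 ± 1506 CPM in CAST and 3.83 ± 1.41 CPM in B6. Meiotic onset genes rose in 14 of 20 (15 adjusted over the list alone; camera adjusted p = 0.134), including Spo11, the enzyme of meiotic DNA breaks, and Meioc (5.32 and 5.12). In the median of this list, replicates 4 and 5 exceeded the other CAST replicates by a log2 ratio of 3.28.

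Without testis CAST replicates 4 and 5, 8115 genes differed (4045 higher, 4070 lower), and germ cell and division genes were lower in CAST. All 14 shared germ cell genes fell in that comparison (camera adjusted p = 3.97e-06, adjusted p = 0.783 with an estimated correlation), as did 11 of 14 mitotic kinesin genes and 13 of 17 mitotic cyclins and kinases (camera adjusted p = 0.00187 for each list, adjusted p = 0.783 with an estimated correlation). Meiotic onset genes then fell in 11 of 20 and rose in 1, Spo11 lost its call (0.30, adjusted p = 0.411 by edgeR), Meioc reversed (-0.73, adjusted p = 0.0740) and the rises of Fbp1 (2.27), Spag17 (2.12) and Rsph1 (2.14) shrank. Gsdma3 was higher in CAST with all replicates and without those (9.78 and 9.998).

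With all replicates, mitotic cyclins and kinases fell in 6 of 17 and rose in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0420, adjusted p = 0.474 with an estimated correlation). Cyclin B1 (Ccnb1) fell by 0.57 ± 0.10, the chromosomal passenger gene Incenp by 0.52 ± 0.07 and the spindle motor gene Kif11 by 0.65 ± 0.10 on the log2 scale, and each held without CAST replicates 4 and 5. Fetal germ cell and pluripotency genes fell in 4 of 13, including Tcl1 (-1.77), and Sall4 (-0.999) fell among the shared germ cell genes. Sertoli genes fell in 6 of 18 and rose in 3, with Dmrt1 (-0.97) and Gata4 (-1.33) among the falls (camera adjusted p = 0.0420 for the fetal germ cell and the Sertoli list, adjusted p = 0.474 and 0.854 with an estimated correlation). The median Sertoli gene was lower in replicates 4 and 5 than in the other CAST replicates by a log2 ratio of -1.36. Interferon response genes fell in 6 of 16 and rose in 1 (camera adjusted p = 0.0420, adjusted p = 0.854 with an estimated correlation), with Oasl2 at -2.29 and Mx2 at 3.13. Cbln4 (34.1 ± 9.41 CPM in B6 and 0.608 ± 0.360 CPM in CAST), Cbln1 (-4.15), Fam155a (-5.25) and Tesc (-3.93) were among the largest falls, and all 4 held without those replicates.

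As a list, Leydig and steroidogenic genes did not pass between the strains in testis. Insl3, a peptide hormone of Leydig cells, rose by 1.201 ± 0.16 on the log2 scale, from 20.4 ± 1.60 to 42.8 ± 7.18 CPM. The steroidogenic enzyme gene Hsd3b1 fell by 0.82 ± 0.20, a call lost with all 30 replicates in the fit (adjusted p = 0.0708 by edgeR; 0.00114 to 0.0708 over the settings tried). Of the 12 measured Leydig and steroidogenic genes 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.762). The median member was lower in CAST replicates 4 and 5 than in the other CAST replicates by a log2 ratio of -0.866, and without those 3 rose and 5 fell.

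Set against either parent, the F1 gonads differed at fewer genes than the parents differed from each other. In ovary 2350 genes separated F1 from B6 (958 higher, 1392 lower) and 1618 separated F1 from CAST (874 higher, 744 lower). By DESeq2 these were 3079 and 2282, against 7462 between the parents, and with all 30 replicates in one fit 908 and 667, against 3794. In testis the counts were 572 (357 higher, 215 lower) and 1946 (639 higher, 1307 lower). By DESeq2 they were 1443 and 5031, against 7915 between the parents, and with all 30 replicates in one fit 1175 and 5824, against 8317. Without ovary B6 replicates 2, 3 and 4 the first count was 586 (409 higher, 177 lower) and without replicates 1 and 5 it was 6120, where the parents differed at 3061 and 8723. The count against CAST was 2291 and 2799 in the same 2 fits. Without testis CAST replicates 4 and 5 the testis counts were 5262 (2633 higher, 2629 lower) and 1993 (1243 higher, 750 lower), against 8115 between the parents. Single replicates moved these counts too. The ovary count against B6 became 1401, 1259, 1389 and 4351 without B6 replicates 2, 3, 4 and 5 and 1519 without F1 replicate 5, and that against CAST became 990 without CAST replicate 1. The testis count against B6 became 343, 330 and 324 without B6 replicates 1, 2 and 3 and 355, 340, 355 and 368 without F1 replicates 1, 2, 3 and 5. Against CAST it became 391, 411, 397, 421 and 449 without F1 replicates 1 to 5 in turn, 4594, 4378 and 4255 without CAST replicates 1, 2 and 3, and 508 and 571 without CAST replicates 4 and 5.

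In the main fit, few genes of the F1 gonads lay off the mean of their parents. This was the mean of the log2 group means of B6 and CAST. It lies below the mean of their levels wherever the parents differ, so an F1 level midway between them can count as higher. In ovary 129 of 17336 genes lay off the log2 mean (103 higher, 26 lower), and in testis 79 of 17638 (69 higher, 10 lower). By DESeq2 the counts were 357 and 449, and with all 30 replicates in one fit 92 and 167. Crip2 was higher in F1 ovary (43.7 ± 5.13 CPM, against 31.5 ± 1.67 in B6 and 35.7 ± 1.94 in CAST), a call lost with all 30 replicates in the fit (adjusted p = 0.355; 5.45e-05 to 0.355 over the settings tried). Scd1, the stearoyl-CoA desaturase, was lower (23.1 ± 1.16 CPM, against 30.3 ± 4.31 and 34.3 ± 5.98; adjusted p = 0.0302 by edgeR). Tgif1 was lower as well (log2 difference -0.24, adjusted p = 0.0313), and both lost their call on leaving out any of 7 replicates (adjusted p = 0.0505 to 0.104). Tmem254a was 1.16 higher on the log2 scale. In F1 testis the arrestin-domain gene Arrdc3 was lower (-0.64 ± 0.09, adjusted p = 0.00343), and Tppp (0.89) and Zfp719 (0.70) were higher, the last 2 with calls lost on leaving out any of 11 and 10 replicates (adjusted p = 0.0511 to 0.157). These counts were among the least stable: 274 in ovary without B6 replicate 5, 245 (215 higher, 30 lower) without B6 replicates 2, 3 and 4 and 2070 without replicates 1 and 5. In testis they were 51 without B6 replicate 2, 47, 44 and 44 without F1 replicates 1, 2 and 3, and 454 (340 higher, 114 lower) without CAST replicates 4 and 5.

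Between testis and ovary, which here also differ in sex and age, Sertoli, Leydig and Y-linked genes were higher in B6 testis. In B6, 8285 of 18937 genes passed, 4006 higher and 4279 lower in testis. Sertoli genes rose in 15 of 18 and fell in 1 (the same when adjusted over the list alone; camera adjusted p = 3.06e-13, adjusted p = 0.00221 with an estimated correlation). Amh was at 363 ± 32.2 CPM in testis and 0.840 ± 0.207 CPM in ovary, and the FSH receptor gene Fshr was 8.47 ± 0.54 higher on the log2 scale. Leydig and steroidogenic genes rose in 11 of 13 and fell in 1 (camera adjusted p = 1.23e-09, adjusted p = 0.000824 with an estimated correlation), including the testosterone enzyme gene Hsd17b3 (8.88) and Insl3 (8.63). All 7 measured Y-linked genes rose (camera adjusted p = 1.30e-09, adjusted p = 2.17e-05 with an estimated correlation), among them Ddx3y (8.32) and Eif2s3y (8.42). Xist, the RNA of the inactive X, stood at 2824 ± 445 CPM in ovary and 7.18 ± 1.083 CPM in testis. Smooth muscle and peritubular genes rose in 7 of 10, such as Myh11 (3.55) and Lmod1 (3.66; camera adjusted p = 0.00193, adjusted p = 0.517 with an estimated correlation).

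The germ cell lists moved in different directions between the B6 gonads. Spermatogonia genes rose in 11 of 19 and fell in 2 in testis (camera adjusted p = 0.000289, adjusted p = 0.00872 with an estimated correlation). Sohlh1, a regulator of spermatogonial differentiation, was 5.54 ± 0.50 higher on the log2 scale, and Neurog3, of undifferentiated spermatogonia, at least 35.4-fold higher against a floor of 3 counts over the B6 ovaries. Fetal germ cell and pluripotency genes fell in 10 of 16 and rose in 2 (camera adjusted p = 0.00470, adjusted p = 0.527 with an estimated correlation), with Dppa3 (-6.76) and Sox2 (-5.38) among them. Shared germ cell genes rose in 8 of 14 (camera adjusted p = 0.00427, adjusted p = 0.656 with an estimated correlation). Ovary B6 replicates 2, 3 and 4 exceeded replicates 1 and 5 in the median of these lists, by log2 ratios of 2.73 for shared and 1.81 for fetal germ cell genes, so the ovary level is a mixture. Without replicates 2, 3 and 4, 13 of 14 shared germ cell genes rose in testis and 7 of 16 fetal ones fell, and without replicates 1 and 5, 3 of 14 shared ones rose and 11 of 16 fetal ones fell. The ovary held more of the pregranulosa genes (12 of 15 lower in testis, 3 higher; camera adjusted p = 0.00194, adjusted p = 0.497 with an estimated correlation), such as Irx3 (-4.99). Msx1 of the meiotic onset list was lower in testis too (-4.50). Erythroid genes were lower in testis in 11 of 12 (camera adjusted p = 4.51e-06, adjusted p = 0.182 with an estimated correlation), led by the embryonic globin Hbb-y (-8.53). Endothelial genes were lower in 10 of 13, including Tie1 (-2.52) and Emcn (-2.77; camera adjusted p = 0.000584, adjusted p = 0.519 with an estimated correlation). The catecholamine enzyme genes Th (-7.69) and Dbh (-7.86) and the growth gene Hmga2 (-7.58) were also lower in testis. Ovary B6 replicates 1 and 5 held more of the catecholamine genes, and without them the differences were -5.31 for Th and -5.80 for Dbh.

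APC/C subunit genes rose in 3 and fell in 7 of 14 in B6 testis against ovary. Anapc15 rose from 24.0 ± 2.67 to 69.7 ± 5.90 CPM (log2 fold change 1.61 ± 0.12) and Cdc16 fell by 0.75 ± 0.09. Anapc5 measured 398 CPM in testis and 464 CPM in ovary (-0.15 ± 0.09, adjusted p = 0.175 by edgeR, and adjusted p = 0.0351 with only the 2 groups compared in the fit, 0.0351 to 0.803 over the settings tried). Kif18a differed by 0.24 ± 0.16 (adjusted p = 0.256). Anapc7 was lower in testis (-0.20 ± 0.08, adjusted p = 0.0376), a call lost without testis replicate 1, 2, 3 or 4 or ovary replicate 5 (adjusted p = 0.0614 to 0.123). In CAST 12039 genes differed between the tissues (7118 higher and 4921 lower in testis), and in F1 8572 (4360 and 4212). The CAST fit moved the median of all genes by 0.15 on the log2 scale, and with only the 2 CAST groups in the fit the count was 7484. Without testis CAST replicates 4 and 5 it was 11712, and in B6 the count was 7027 without ovary replicates 2, 3 and 4 and 6726 without replicates 1 and 5.

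The strain difference itself depended on the tissue for 4704 of 18937 genes, 3273 with a larger CAST over B6 ratio in testis and 1431 with a smaller one, around a median shift of 0.14 on the log2 scale. With only the groups compared in the fit the count was 2413 (1656 and 757). Cbln4 and Fam155a were lower in CAST testis but not in CAST ovary, with a difference between the tissues of -7.09 ± 0.51 and -5.58 ± 0.74. The peptidase gene Lvrn measured 17.5 ± 1.72 CPM in B6 testis and 1.10 ± 0.531 CPM in CAST testis, against 0.422 ± 0.176 and 1.29 ± 0.373 CPM in ovary. Prokr2, a receptor of prokineticins, differed by -4.98 ± 0.77. The largest positive differences were of Lypd4 (13.96), Ccdc192 (11.03), Dmrtc2 (10.92), Mroh4 (10.85) and Spesp1 (10.51). Without ovary B6 replicates 2, 3 and 4 and testis CAST replicates 4 and 5 the count was 2904 (1478 higher, 1426 lower), the 4 negative differences held (Cbln4 -6.22, Lvrn -5.69, Fam155a -4.23 and Prokr2 -3.64) and none of the 5 positive ones passed by edgeR (adjusted p = 0.603 to 1). Without the ovary replicates alone it was 1261. The calls of Ccdc192 and Mroh4 were also lost on leaving out any of 14 and 17 single replicates (adjusted p = 0.0517 to 0.241).

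Within the F1 gonads both alleles share one cell environment, and most genes skewed in both tissues favoured the same parent in each. In ovary 1427 of 12764 informative autosomal genes were skewed (629 toward the CAST allele, 798 toward B6) and in testis 2273 of 12705 (1005 and 1268). Among 11792 genes tested in both, 749 were skewed in both tissues, where independent lists would share 239.8, and 729 of the 749 favoured the same parent. Single replicates moved the counts, to 772, 694 and 807 in ovary without F1 replicates 1, 3 and 4 and to 1493 in testis without F1 replicate 5. The cross ran in one direction, so an effect of the allele's strain and of the parent it came from cannot be separated. Beyond the informative filter, whether the counting itself favoured an allele of a gene in both tissues was not tested.

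Imprinted genes showed the strongest skews. Of 20 informative genes listed with an active paternal copy, 18 favoured the paternal CAST allele in ovary and 17 in testis. Of 10 and 11 listed with an active maternal copy, 10 and 9 favoured the maternal B6 allele (19, 19, 10 and 10 in the same order when adjusted over the list alone). Mest gave 99.6 ± 0.193% CAST allele (SD, n = 5), Peg3 98.8 ± 0.774% and Peg10 98.9 ± 0.535% in ovary, and Sgce 99.8 ± 0.429% in testis. At the other end stood Zim1 (0.733 ± 0.149%), H19 (0.883 ± 0.886%), Grb10 (2.30 ± 0.319%), Cdkn1c (4.52 ± 0.160%) and Igf2r (6.54 ± 0.9495%) in ovary. Rtl1, listed as paternal, was at 48.1 ± 19.5% in ovary and favoured B6 in testis (19.3 ± 4.34%, adjusted p = 0.000503 by edgeR). That call was lost with only the lower-numbered library of each pair (adjusted p = 0.296). Rtl1 has an antisense transcript from the maternal copy, and its value is uncertain since the sources do not say that counting used strand. Osbpl5 was only mildly B6-skewed (39.5 ± 2.003% in ovary, 42.0 ± 5.03% in testis), and the testis call was lost without F1 replicate 1, 2, 4 or 5 (adjusted p = 0.0638 to 0.0817).

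**Figure D4:**
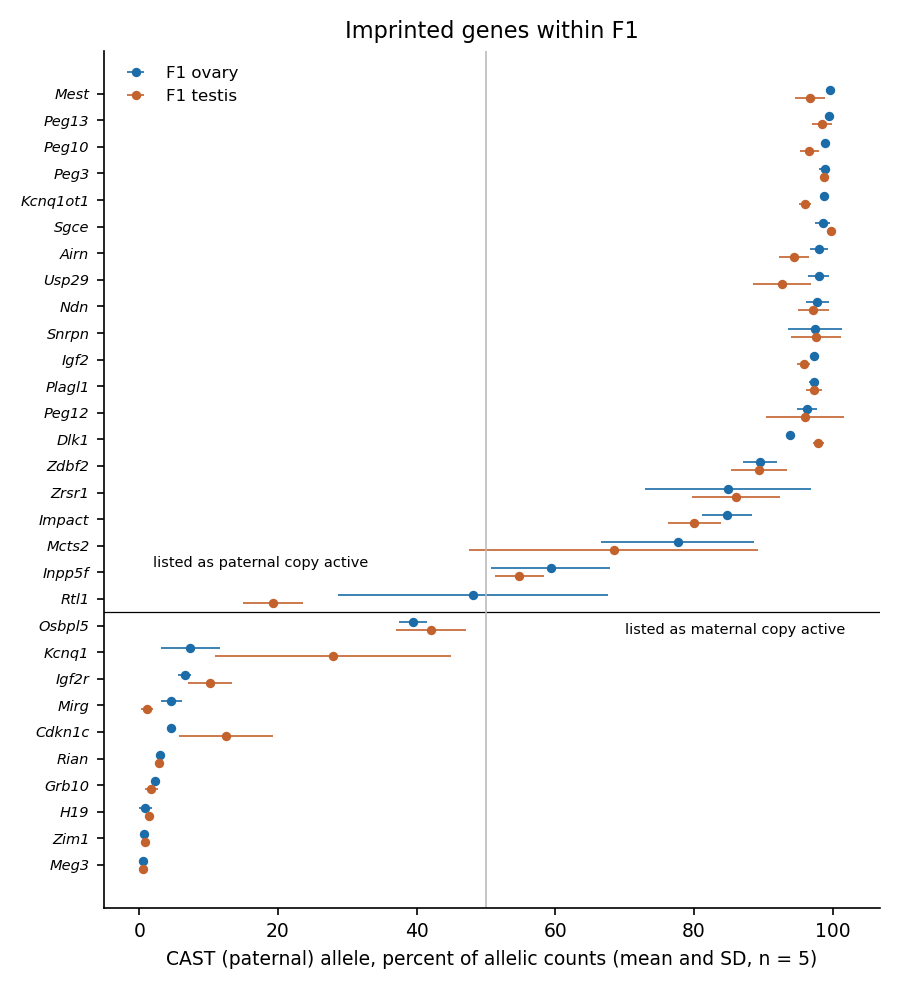
Percent of allelic counts from the CAST allele, which is the paternal one, for informative imprinted genes in F1 ovary and F1 testis (mean and SD, n = 5), with the genes listed as paternally active above the line. Mest stood at 99.6% and Zim1 at 0.733% in ovary.

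Outside the imprinted list the B6-skewed genes of F1 ovary included Slfn9 (9.15 ± 4.14% CAST allele), the interferon gene Ifit2 (10.96 ± 3.43%), Asb4 (11.1 ± 1.89%), a neighbour of Peg10 and Sgce on chromosome 6, and Rec8 (12.8 ± 14.7%, adjusted p = 0.0423 by edgeR). Rec8 lost its call without F1 replicate 1, 2, 4 or 5 (adjusted p = 0.0640 to 0.117). Whether Asb4, which is not on the list, is itself imprinted was not tested. In testis Sgpp2 (3.77 ± 1.82%), Tesc (7.70 ± 1.51%), Cbln4 (7.95 ± 3.88%) and Sfn (11.2 ± 9.87%) favoured B6. Among APC/C genes, Cdc23 favoured B6 in both tissues. Its CAST allele share was 42.3 ± 2.32% in ovary (adjusted p = 0.00552 by edgeR) and 43.3 ± 2.80% in testis (adjusted p = 0.0112). The testis call was lost with only the lower-numbered library of each pair (adjusted p = 0.102). Anapc2 favoured CAST in testis (58.7 ± 3.29%, adjusted p = 0.00414), with 55.0 ± 3.61% in ovary (adjusted p = 0.0640). Cdc26 favoured B6 in testis (44.9 ± 2.35%, adjusted p = 0.0447), a call lost without any one of the 5 F1 replicates (adjusted p = 0.0575 to 0.124). Anapc5 was at 47.6 ± 1.83% in ovary (adjusted p = 0.112) and 49.2 ± 1.74% in testis (adjusted p = 0.527). Anapc7 was at 51.7 ± 2.25% and 53.2 ± 4.55%, and Kif18a at 43.5 ± 6.32% and 49.5 ± 3.94%, with none of these past the threshold. On chromosome 5, 11.9% of 884 informative genes were skewed in ovary against 11.1% of 11880 on other autosomes (two-sided Fisher's exact test, p = 0.507), and 17.5% of 893 against 17.9% of 11812 in testis (p = 0.786).

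The allelic ratio within F1 was set against the ratio between the parental strains, to see which strain differences appear between alleles in one cell. Of the genes skewed in F1 ovary, 1206 of 1427 (84.5%) had a parental ratio of the same sign, whether or not it passed, and in testis 1688 of 2273 (74.3%). Across all informative genes, which are not independent replicates, the ratios correlated at a Pearson r of 0.447 in ovary and 0.334 in testis, and at 0.534 and 0.515 without ovary B6 replicates 2, 3 and 4 and testis CAST replicates 4 and 5. The ovary r was 0.349 without ovary B6 replicates 1 and 5, where 80.1% of skewed genes had the same sign. The ratios differed at 520 genes in ovary (241 with a higher parental ratio, 279 with a lower) and 178 in testis (79 and 99), or 1248 and 640 with no informative filter. Genes of the imprinted lists were among the largest differences, and so was Asb4, which lies near Peg10 and Sgce. In ovary these were Mest (-8.08 ± 0.35), Zim1 (7.32 ± 0.20), Grb10 (5.97 ± 0.29) and Asb4 (4.74 ± 0.64). In testis they were Sgce (-9.67 ± 0.86) and Peg3 (-7.12 ± 0.89). In testis Gpd1, a glycerol phosphate enzyme gene, had a parental ratio 3.95 above its allelic one, Plin4, a lipid droplet gene, 4.51 and Hp, haptoglobin, 3.81. The calls of Plin4 and Hp were lost on leaving out any of 8 and 3 replicates (adjusted p = 0.0501 to 0.103). Among APC/C genes the ratios differed for Anapc2 in testis (-0.76 ± 0.11, adjusted p = 0.00283 by edgeR) and for Cdc23 (0.33, adjusted p = 0.0318) and Cdc26 (0.40, adjusted p = 0.0292) in ovary. The calls of Cdc23 and Cdc26 were lost on leaving out any of 9 and 6 replicates (adjusted p = 0.0513 to 0.0637) and without B6 replicates 2, 3 and 4 (adjusted p = 0.292 and 0.276). Without ovary B6 replicates 2, 3 and 4 the ovary count was 148 (77 and 71) and without replicates 1 and 5 it was 2887, and without testis CAST replicates 4 and 5 the testis count was 1456 (723 and 733). The ovary count became 790, 248, 241, 243 and 1690 without B6 replicates 1 to 5 in turn and 268 and 259 without CAST replicates 1 and 2. The testis count became 106, 95, 84, 100 and 118 without B6 replicates 1 to 5 and 111, 108, 117, 113 and 110 without F1 replicates 1 to 5.

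**Figure D5:**
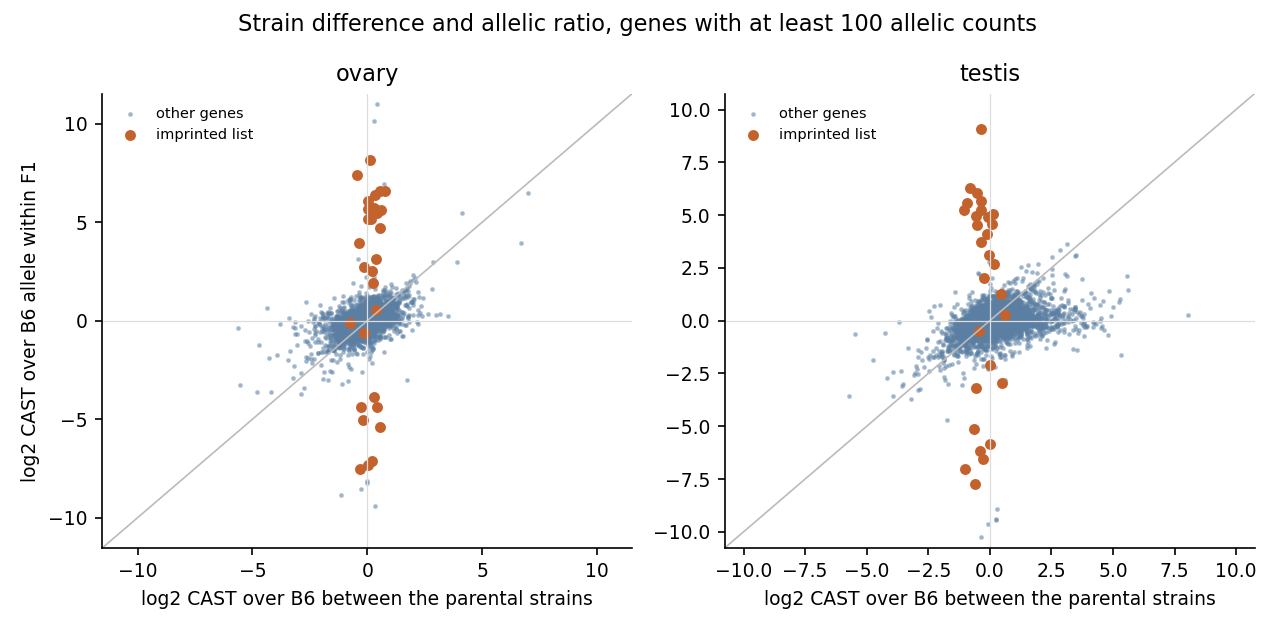
Log2 ratio of the CAST over the B6 allele within F1 against the log2 fold change of CAST over B6 between the parental strains, 1 point per informative gene with at least 100 allelic counts, in ovary and testis, with the line of equal ratios. Most genes of the imprinted lists, in orange, had a parental difference smaller than their allelic ratio, which reached 8.18 in ovary (Mest). Their parental log2 differences ran from -0.741 (Rtl1) to 0.75 (Peg10) in ovary and from -1.04 (Plagl1) to 0.635 (Inpp5f) in testis.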

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

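The tests of CAST allele share and of mesonephros genes, and the comparisons that leave out ovary B6 replicates 2, 3 and 4 or testis CAST replicates 4 and 5, were chosen only after the result was seen.

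Testis CAST replicates 4 and 5 stood apart from the other CAST testes by high meiotic genes and low Sertoli and stromal genes. Their CAST share of autosomal allelic counts was at least 96.4%, so they were not animals of another strain. The median log2 ratio of the spermatogonia list was -0.198 (7 genes above 0 and 9 below), not raised as a larger share of spermatogonia at the same age would predict. It differed from that of the meiotic onset list by -3.478, which argues against that explanation. High meiotic genes had set these replicates apart, however, so the meiotic part of this difference is no separate evidence. An age above 5 days is a candidate explanation, since the median log2 ratio of 5 Sertoli maturation genes was 3.05, with Rhox5 at 15.4 against 0.349 CPM and Eppin at 33.3 against 3.58 CPM, although Cst12 was lower (103 against 178 CPM). Ldhc (1705 and 1700 CPM), Hspa2 (1319 and 1300 CPM) and Piwil1 (988 and 926 CPM) were also high in replicates 4 and 5. In CAST replicates 1 to 3 they were at most 1.6, 15.2 and 2.85 CPM. No prediction had been made for these genes. Whether replicates 4 and 5 held spermatids stays open by the median over 7 spermatid genes, 1.252 CPM in replicate 4 and 0.621 CPM in replicate 5. Prm1 and Prm2 were at most 0.248 CPM there.

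Ovary B6 replicates 2, 3 and 4 stood apart from replicates 1 and 5 by high germ cell and pregranulosa genes. Less gonad and more adjoining tissue in replicates 1 and 5 would have lowered the mesonephros genes in the other 3, but their median log2 ratio was 0.951. A later stage within the labelled span of 12.5 to 13.5 days is a candidate explanation, since the lowest ratio of definitive to embryonic beta-globin in replicates 2, 3 and 4 was 3.21 times the higher of replicates 1 and 5. The F1 and CAST ovaries had ratios of 0.1035 to 0.287, nearer to those of replicates 1 and 5 (0.234 and 0.103). Sympathetic and adrenal cells, whose neural crest genes were higher in replicates 1 and 5 (median log2 ratio -2.40), were not tested apart from this.

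The CAST share of mitochondrial allelic counts in ovary F1 replicate 1 was 1.299%, against 0.164% to 0.239% in the other F1 ovaries, which carry B6 mitochondria. Admixed CAST RNA might give this, and would also raise the CAST share of genes expressed from the maternal B6 copy. Over 8 such imprinted genes the median excess was 0.205 percentage points, and 4 of the 8 were highest in replicate 1, too little to decide. No biological explanation was tested.

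In 69 groups of replicates, 3 had a value far from the others, where chance gives about 1 in 20. Besides the mitochondrial share these were the total of ovary F1 replicate 3, 31.1 M expected counts (others at most 20.2 M), and the CAST share of Xist in ovary B6 replicate 5, 1.19% (0.802% to 0.889% in the others).

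The strain effect differed between testis and ovary by the test of the difference itself for 9 named genes. It was higher for Lypd4 (13.96, adjusted p = 0.00136 by edgeR), Ccdc192 (11.035, adjusted p = 0.0426), Dmrtc2 (10.92, adjusted p = 0.000579), Mroh4 (10.85, adjusted p = 0.0494) and Spesp1 (10.51, adjusted p = 0.00504). It was lower for Cbln4 (-7.09), Fam155a (-5.58), Lvrn (-5.555) and Prokr2 (-4.98; adjusted p = 1.53e-09 to 0.00012). Without ovary B6 replicates 2, 3 and 4 and testis CAST replicates 4 and 5 the 4 lower ones held and none of the 5 higher ones passed (adjusted p = 0.603 to 1), with Mroh4 at 0.27 and Spesp1 at -0.14. The calls of Ccdc192 and Mroh4 were also lost on leaving out any of 14 and 17 single replicates (adjusted p = 0.0517 to 0.241). Tissue, sex and age are confounded in these differences.

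X-linked genes, which the allelic tests left out, gave a CAST share of 58.0 ± 4.57% in F1 ovary (SD, n = 5), against 5.79 ± 0.296% in B6 ovary.

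Other splits of the same samples were drawn for each count of genes. For CAST against B6 in ovary, 1 of 100 splits, the real one, reached its count (6650, highest other 2924). The same held for F1 against B6 (2350, 2027) and F1 against CAST in ovary (1618, 1). It also held for CAST against B6 (5695, 3220), F1 against B6 (572, 1) and F1 against CAST in testis (1946, 2). By a share under 0.05, chance can be excluded for these counts, save that of F1 against B6 in ovary. Its share was under 0.05 too, but with a narrow margin. That real count fell to 1259 without B6 replicate 3, below the 2027 of another split, so chance is not firmly excluded for it. For F1 against the parental mean, 3 of 100 splits reached 129 in ovary (highest other 1035) and 12 of 100 reached 79 in testis (highest other 3351). The ovary share of splits was under 0.05 and the testis share was not. As other splits reached far more genes than the real one, chance is not firmly excluded for either count. Those splits point to a structure of the samples in both tissues. Among 60 splits, only the real one reached the tissue counts in B6 (8285, highest other 1106), CAST (12039, 7329) and F1 (8572, 654) and the strain-by-tissue count (4704, 3132). Chance can be excluded for these too. Only the real split also reached the count for parental against allelic ratios by limma on 5 ratios of either kind, in ovary (334, 2) and testis (92, 0). These are not the edgeR counts of 520 and 178. The parental ratios were also taken between same-numbered CAST and B6 replicates, which the labels do not pair. For the edgeR counts the splits therefore cannot decide about chance. In CAST the other splits had a median of 1902 genes, which points to a structure of the samples. For the allelic tests the 16 exchanges of alleles are too few for a share under 0.05 (ovary 1427, highest other 0; testis 2273, highest other 0).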

How the results depend on the processing

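The comparisons without ovary B6 replicates 2, 3 and 4, without ovary B6 replicates 1 and 5, without testis CAST replicates 4 and 5 and without ribosomal RNA-like loci are the tests chosen only after the result was seen. Over 16 results, 248 of 369 counts and shares kept their reading under an alternative and 121 moved. Of 2888 values for 149 gene results, 2647 kept their call, 217 lost it, 9 gained it, 11 changed sign with no call in either fit and 4 changed sign with a call in only one of them.

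A log2 change of at least 1 left 2104, 697, 485 and 80 genes in ovary (CAST against B6, F1 against B6, F1 against CAST, F1 against the parental mean), and 3101 and 310 in testis for the first 2. It left 4576, 6917 and 4638 between the tissues in B6, CAST and F1, and 2961 for strain by tissue. For alleles it left 393 and 601 in ovary and testis, and for parents against alleles 219 and 108. DESeq2 called 357 genes off the parental mean in ovary, and in testis 1443 (F1 against B6), 5031 (F1 against CAST) and 449 (parental mean). With all 30 replicates in a fit the ovary counts were 3794, 908 and 667 for CAST against B6, F1 against B6 and F1 against CAST. In testis they were 1175 and 5824 for the latter 2 and 167 for the parental mean. With only the compared groups in a fit, 7484 genes passed between the CAST tissues and 2413 for strain by tissue. No filter on low counts gave 342 for F1 against B6 in testis and 50 for the parental mean there. No informative filter gave 1248 and 640 for parents against alleles in ovary and testis.

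With only the lower-numbered library of each pair, counts fell to 1519 and 991 (F1 against B6 and CAST in ovary), 314 and 1090 (the same in testis), 425 and 879 (alleles) and 293 and 97 (parents against alleles). With only the higher-numbered one they fell to 980 (F1 against CAST in ovary), 342, 1103 and 50 (F1 against B6, CAST and the parental mean in testis). A replicate block, as if equal replicate numbers were paired, gave 3331, 311, 339 and 31 in testis (CAST against B6, F1 against B6, CAST and the parental mean). Parents against alleles in testis without a replicate block gave 328. The labels do not say that a number marks a litter or batch, and in no 2 groups did all 5 same-numbered pairs correlate above 0.1. The nearest were the F1 and CAST ovaries, with 4 of 5 pairs above 0.1 and 7 of 10 samples best correlated with their own number, and the lowest value was -0.278 in testis.

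Leaving out ovary B6 replicates 2, 3 and 4 gave 3061, 586 and 245 in ovary (CAST against B6, F1 against B6, parental mean), 148 for parents against alleles and 1261 for strain by tissue, or 2904 with testis CAST replicates 4 and 5 out too. Leaving out ovary B6 replicates 1 and 5 gave 6120, 2799 and 2070 (F1 against B6, CAST and the parental mean) and 2887 for parents against alleles. Without testis CAST replicates 4 and 5 the counts were 5262 (F1 against B6), 454 (parental mean) and 1456 (parents against alleles). Of the gene lists, camera called 3 of 27 in ovary, 4 of 28 in testis and 13 of 28 between the B6 tissues, and 0, 0 and 4 with an estimated correlation. It called 1 in ovary without B6 replicates 2, 3 and 4 and 11 without replicates 1 and 5. The share of chromosome 5 genes called was 31.3% in ovary and 31.6% in testis by DESeq2, against 32.0% and 32.9% of genes on the other autosomes. It was 47.9% in ovary without B6 replicates 1 and 5 and 43.6% in testis without CAST replicates 4 and 5, against 48.7% and 44.5%. It was 32.7% among protein-coding genes in testis. For alleles in testis it was 4.93% with a log2 change of at least 1 and 18.4% among protein-coding genes. Cdc26 in testis, with no call in the main fit (-0.08), gained one at 0.24 without testis CAST replicates 4 and 5. The calls of Meioc in testis (-0.73) and Mroh4 in strain by tissue (-0.52) were lost with a change of sign there, and that of Spesp1 in strain by tissue (-0.14) with ovary B6 replicates 2, 3 and 4 out too (adjusted p = 0.0740 to 1 by edgeR for the 3).

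Leaving out each replicate in turn gave 5424 to 7756 genes (CAST against B6), 1259 to 4351 (F1 against B6), 990 to 1530 (F1 against CAST) and 93 to 274 (parental mean) in ovary, and 4177 to 7081, 324 to 561, 391 to 4594 and 44 to 89 in testis. The ranges were 7586 to 7957, 11258 to 12432 and 7894 to 8148 between the tissues in B6, CAST and F1, 3525 to 6091 for strain by tissue, 694 to 963 and 1493 to 1678 for alleles in ovary and testis, and 241 to 1690 and 84 to 250 for parents against alleles.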

Other observations

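The test of the CAST share of Xist described here was chosen only after the result was seen.

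In the F1 ovaries the X chromosomes were not expressed equally. The CAST share of X-linked allelic counts was 54.5% to 64.3% in the 5 replicates, and that of Xist, which is made by the inactive X, was 27.7% to 41.9%. The replicate with the highest X-linked CAST share, replicate 1, had the lowest CAST share of Xist. In the F1 testes, which carry only the maternal X, the X-linked CAST share was 6.45 ± 0.404% (SD, n = 5), close to the 5.79 ± 0.219% of B6 testis.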
